A study of Mus musculus with 4 samples.

How the data were processed

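Single-cell RNA sequencing libraries of mouse epidermis were taken from the deposited files, 2 from skin in which expansion was induced (expanded) and 2 from skin with an expander in which it was not (non-expanded). The groups and the batch numbers, 1 and 2, come from the sample titles, because the treatment field reads the same for all 4 libraries. Per the labels, epidermal sheets were released with 0.4% dispase at 4 °C, cells were freed with 0.25% trypsin, and cells that excluded propidium iodide and took up DyeCycle Violet were sorted as live single cells. The deposited matrices hold UMI counts per gene and barcode, whole numbers without normalization, made by the authors with Cell Ranger. Per the file headers, batch 1 was processed with version 4.0.0 and batch 2 with version 5.0.0, whereas the authors' processing notes name 4.0.0 for every library. Those notes give the mm10 genome, do not state the annotation release, and the deposited gene list includes a tdTomato sequence. Gene coordinates were taken from GENCODE vM21 (GRCm38) by gene identifier.

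Barcodes with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs were kept. Scrublet in scanpy 1.11.5 scored doublets within each library. Its automatic threshold marked 5 barcodes in expanded replicate 1 and 0 in each other library, so the planned share of 0.8% per 1000 barcodes was removed, which took out 10, 371, 186 and 314 barcodes from expanded replicates 1 and 2 and non-expanded replicates 1 and 2. Some barcodes occurred in both libraries of a batch, 75 in batch 1 and 1060 in batch 2, against 4 to 14 for pairs from different batches. The smaller copy held a median of 2.75% of the larger copy's UMIs in batch 1 and 1.02% in batch 2. Among the kept cells 3, 11, 17 and 6 were such smaller copies, and leaving them out was added as an alternative.

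Clustering used 2000 variable genes, 30 principal components, 20 neighbours and the Leiden method (leidenalg 0.10.2) at a resolution of 1.0. The classes were settled on the third attempt, before any test between the groups was run. In the attempt that scaled genes over all libraries, clusters split by library. In the next, which centred and scaled genes within each library, several keratinocyte clusters matched no marker list. The classes used here also left the response gene lists out of the clustering genes and added 100 CPM before fold changes between clusters. Cell-cycle genes, Lgr6 and tdTomato were left out of the clustering genes in every attempt. The 2 earlier attempts were kept as added alternatives. Clusters were named from marker lists by their 10 highest-ranked genes, under a rule completed after the clusters were seen. One cluster, with a median depth of 0.128 of its library's, met no class by that rule and was left unnamed. A class was tested if each library held at least 20 of its cells.

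UMI counts were summed per library and class. edgeR 4.0.16 with limma 3.58.1 in R 4.3.3 tested the groups with filterByExpr, TMM scaling and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM given with fold changes are scaled by TMM, and CPM called unscaled are not. Differences between effects in 2 classes were tested as a class by group interaction with the library as a block. The 29 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry, and gene calls were also adjusted over each list alone. Shares were compared by exact two-sided permutation tests on libraries, whose smallest possible p with 2 against 2 was 0.333. Intervals on single shares are 95% Wilson intervals for classes and exact Clopper-Pearson intervals for detection. Intervals and limits cover counting error only. A count of 0 was given the limit that 3 counts allow. Detection and cycling shares used cells thinned to 2000 UMIs, with shallower cells left out. Cycling cells were those with at least 3 UMIs over the G2 and M phase list. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

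The tests, lists, markers, named-gene rule and first set of alternatives were fixed before the data were examined. Genes named in a class were the 12 largest rises and 12 largest falls past the threshold, with the same direction in both batches and a mean of at least 20 CPM. Where none passed, the 5 smallest unadjusted p in each direction were given as values. Up to 4 members of each list past the threshold, a fixed set of basal genes, and the 8 largest rises and falls of an interaction were named too; 2 members per list are given. After the data were seen the same rule was applied to the fit with a replicate block, and the comparison of basal with hair follicle keratinocytes and the lists in hair follicle keratinocytes were added.

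Batch numbers pair 1 library of each group. Correlations across genes of the batch deviations in the groups were 0.304 in basal, 0.176 in suprabasal, 0.164 in hair follicle and 0.252 in all keratinocytes, and genes are not independent replicates. The reported fits have no batch term, and the fit with a replicate block is given where it changed a call or moved a count by over 1.5 times. Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, each library left out in turn, a stricter cell filter (1000 genes, 2000 UMIs, 10% mitochondrial UMIs), doublets kept, a Leiden resolution of 0.5, thinning to 2000 or 4000 UMIs, no thinning and a cycling minimum of 2 UMIs. Alternatives chosen after seeing the data were leaving out swapped barcodes, leaving out clusters led by mitochondrial or ribosomal RNA, the 2 earlier clusterings, leaving every called gene out of the clustering genes, and calling cycling cells by Mki67 or Top2a.

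The tests were checked on simulated counts with the depths of these libraries and known changes. In basal keratinocytes edgeR recovered 3% of changes of 2-fold, 67.2% of 4-fold and 84.8% of 8-fold. The same 3 percentages were 10.6, 58.2 and 93.9 in suprabasal, 18.2, 83.3 and 97 in hair follicle and 4.5, 68.3 and 87.7 in all keratinocytes. They were 1.6, 25.8 and 60 for the difference between basal and suprabasal effects and 3.1, 29.5 and 71.9 for that between basal and hair follicle effects. camera recovered a simulated 2-fold shift of the hypoxia response list in all 3 classes and called 0 other lists. The simulated genes varied independently and without a batch effect, whereas the estimated correlation in basal cells was 0.919 for S phase. This check therefore cannot show how many lists correlated genes would call falsely. T cells and antigen-presenting cells were not tested, with as few as 19 and 0 cells in a library, and basal cells with an Lgr6 UMI were not compared with others, because an expanded library held 3.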

Results

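Epidermal cells of 8-week-old male mice were compared between skin under induced expansion (expanded) and skin with an expander and no induced expansion (non-expanded). All mice carried an Lgr6-EGFP-Ires-CreERT2 allele and a tdTomato reporter. Each group had 2 libraries, 1 per batch, and the labels did not say whether they came from separate animals. Expanded replicates 1 and 2 and non-expanded replicates 1 and 2 gave 1539, 8597, 5913 and 7902 barcodes, of which 789, 5021, 3753 and 4646 were kept. Mitochondrial UMIs above 15% were found in 44.9%, 24.9%, 30.6% and 23.6% of barcodes. Median UMIs per kept cell were 17272, 23624, 4468 and 16717.5, so depth differed most for non-expanded replicate 1.

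Basal, suprabasal and hair follicle keratinocytes made up most kept cells, and the basal share was lower and the suprabasal share higher in both expanded libraries. The classes are named from markers: Krt14, Krt5, Col17a1 and cycling genes for basal, Krt1, Krt10, Krtdap, Lor and Flg for suprabasal, and Krt79, Cd34 and Sostdc1 among those for hair follicle. Basal cells formed 46.7 ± 1.68% of expanded and 55.9 ± 1.79% of non-expanded cells (mean ± SD, n = 2 each), a difference of -9.23 points (-11.7 in batch 1, -6.77 in batch 2; exact permutation p = 0.333). Suprabasal cells formed 33.5 ± 2.04% against 22.0 ± 4.60%, a difference of 11.6 points (13.4 and 9.75; exact permutation p = 0.333), and hair follicle cells 10.2 ± 2.75% against 15.2 ± 6.14% (-4.99 points; -7.39 and -2.58; exact permutation p = 0.667). With 2 libraries per group no share could reach p under 0.333. With doublets kept the basal difference was -6.416 points, -12.452 in batch 1 and -0.38 in batch 2. Basal and suprabasal shares kept their direction when any 1 library was left out. The clustering scaled over all libraries gave 4.394 points for basal and -4.017 for suprabasal, so the direction rested on how the classes were built and named. In that clustering the rule named cluster 2 neutrophil, although Krt14 and Krt1 were high in it. It held 97 and 1117 expanded and 6 and 1 non-expanded cells. Cluster 17, high in Krt14 and Krt5, was left unnamed, with 2 and 11 against 50 and 1076 cells. These cells counted in no keratinocyte class, and shares with them put back were not computed. T cells formed 2.09 ± 2.42% and 2.30 ± 0.817% (exact permutation p = 1), with opposite directions in the 2 batches (0.925 and -1.34 points). The unnamed cluster of shallow cells held 6.44% of expanded and 2.53% of non-expanded cells.

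**Figure D1:**
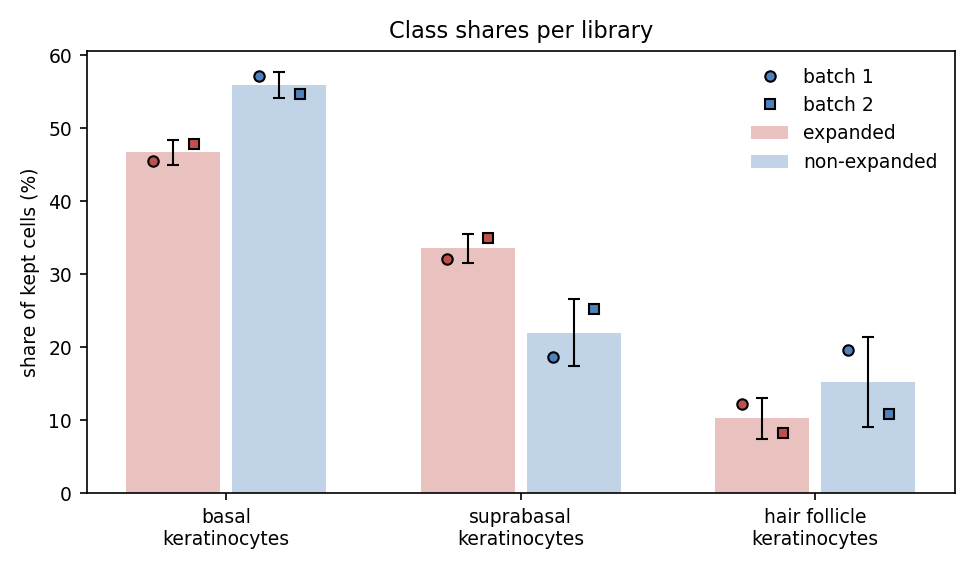
Share of kept cells in basal, suprabasal and hair follicle keratinocytes per library, with bars at the group mean ± SD (n = 2 libraries per group). The basal mean was 46.7% in expanded and 55.9% in non-expanded skin, the suprabasal mean 33.5% and 22.0%.

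In basal keratinocytes the antimicrobial genes S100a8 and S100a9 rose over 100-fold in expanded skin, and Mt4 and Guca2a fell. S100a9 went from 10.99 ± 4.35 to 2334 ± 835 CPM (log2 fold change 7.71, SE 0.53, edgeR adjusted p = 0.0559) and S100a8 from 9.06 ± 4.01 to 2040 ± 882 CPM (7.79, SE 0.59, edgeR adjusted p = 0.0591). Sprr2a3 (4.53; reads shared with its near copies Sprr2a1 and Sprr2a2 cannot be told apart), Cd24a (2.34) and Mgst2 (2.33) rose. Mt4 fell from 159 ± 26.4 to 4.31 ± 2.66 CPM (-5.32, edgeR adjusted p = 0.0793), and Guca2a (-2.60), Aknad1 (-2.82) and Sema3d (-2.69) fell too. These genes were among those with the smallest unadjusted p in each direction. They moved the same way in both batches, and each passed with the replicate block (edgeR adjusted p 0.000805 for S100a8 and S100a9 to 0.00859 for Aknad1). Of the other 10 neutrophil markers, Retnlg, Ly6g, Ltf, Trem1 and Camp had 0 UMIs in basal cells of every library, and Csf3r and Ngp stood at 0.09 unscaled CPM or less. Cxcr2 stood at 0.56, 3.69, 0.64 and 2.62 unscaled CPM, Mmp9 at 25.01, 1.63, 0 and 5.49, and Il1r2 at 117, 85.2, 272 and 86.4. The libraries, with 359 and 2404 expanded and 2146 and 2539 non-expanded basal cells, differed in the mix of basal clusters. Cluster 10 held 53 and 883 expanded and 17 and 8 non-expanded cells. Cluster 3 held 10 and 147 against 67 and 868, most of them from non-expanded replicate 2. Cluster 15 held 75 and 100 against 1053 and 243, most of them from non-expanded replicate 1.

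None of the 13322 genes tested in basal keratinocytes passed by edgeR (0 at adjusted p < 0.05; 1013 at unadjusted p < 0.05), whereas DESeq2 called 236 and edgeR without the filter on low counts 532. With the batch as a replicate block edgeR called 136 genes, 61 higher and 75 lower. Leaving out expanded replicate 1 gave 85 genes, expanded replicate 2 18, non-expanded replicate 1 920 and non-expanded replicate 2 587. Those fits leave a single library in a group, so passing in them is not taken as support. Over all alternatives the adjusted p of S100a9 and S100a8 in basal keratinocytes, by edgeR or DESeq2, reached 0.642. Among the genes past the threshold with the block, Lcn2 (6.60), 2610528A11Rik (3.93), Tmem176a (3.11), Them5 (3.11), Sostdc1 (3.09), Ehf (2.61), Egln3 (2.57), Stfa3 (2.46) and Mgst1 (2.40) rose. Hopx (-2.42), Crip1 (-2.31), Nr1d1 (-2.24), Cnn2 (-2.11), Gsn (-2.07), Krt15 (-1.95) and Serpinb2 (-1.88) fell in that fit. These fold changes are from the fit without the block. Krt15 in basal keratinocytes went from 3912 ± 3847 to 1014 ± 1071 CPM, with edgeR adjusted p = 0.806 without and 0.0291 with the block (range over alternatives 2.56e-05 to 1).

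Lgr6 was almost absent from expanded basal keratinocytes and present in non-expanded ones in both batches. The 359 and 2404 expanded basal cells held 6 and 3 Lgr6 UMIs, the 2146 and 2539 non-expanded ones 257 and 650. As CPM without scaling this was 0.843 (95% counting interval 0.309 to 1.84) and 0.048 (0.01 to 0.14) against 23.4 (20.6 to 26.5) and 10.02 (9.27 to 10.8). The ratio of expanded to non-expanded was 0.0360 (0.0131 to 0.0795) in batch 1 and 0.00478 (0.000984 to 0.0140) in batch 2. After thinning to 2000 UMIs, 0 of 354 and 0 of 2400 expanded basal cells had a UMI (limits from 3 counts 0.847% and 0.125%), against 4.28% (3.43 to 5.27) and 2.53% (1.95 to 3.22) of non-expanded ones, a difference of -3.40 points (exact permutation p = 0.333). Without thinning the difference was -13.1 points, and 5, 4, 160 and 8 cells were too shallow to thin. Thinned T cells, taken as background, had 0 Lgr6 UMIs in 27, 9, 45 and 67 cells. Median UMIs were 4203, 1944, 1787 and 3680 in T cells and 18644, 24906, 4336.5 and 18493 in basal cells. Without thinning, T cells had 0 Lgr6 UMIs too, with upper 95% bounds of 26.6, 50.1, 13.8 and 11.2 CPM. Only in non-expanded replicate 1 did the bound lie below the basal level, so T cells set no background in the other libraries.

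By edgeR, Lgr6 in basal keratinocytes had a log2 fold change of -6.36 (SE 1.18; 0.447 ± 0.561 against 16.4 ± 9.20 CPM) and an adjusted p of 0.243, with DESeq2 0.0539 and with the replicate block 0.0172 (range over alternatives 1.37e-26 to 0.933). Leaving out 1 library leaves a single library in a group, so whether Lgr6 passed in such a fit is not taken as support. Its value stayed negative in every alternative, from -9.005 to -4.227. The fall was larger in basal than in hair follicle keratinocytes, where unscaled CPM of Lgr6 were 7.87 and 1.45 in expanded and 8.72 and 5.26 in non-expanded libraries. The hair follicle ratio was 0.903 (0.446 to 1.73) in batch 1 and 0.275 (0.146 to 0.493) in batch 2. For Lgr6, basal effect minus hair follicle effect, a comparison added after the data were seen, the log2 difference was -5.14 (SE 0.585, edgeR adjusted p = 0.0194; 1 without the library block; range over alternatives 5.96e-07 to 1).

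**Figure D2:**
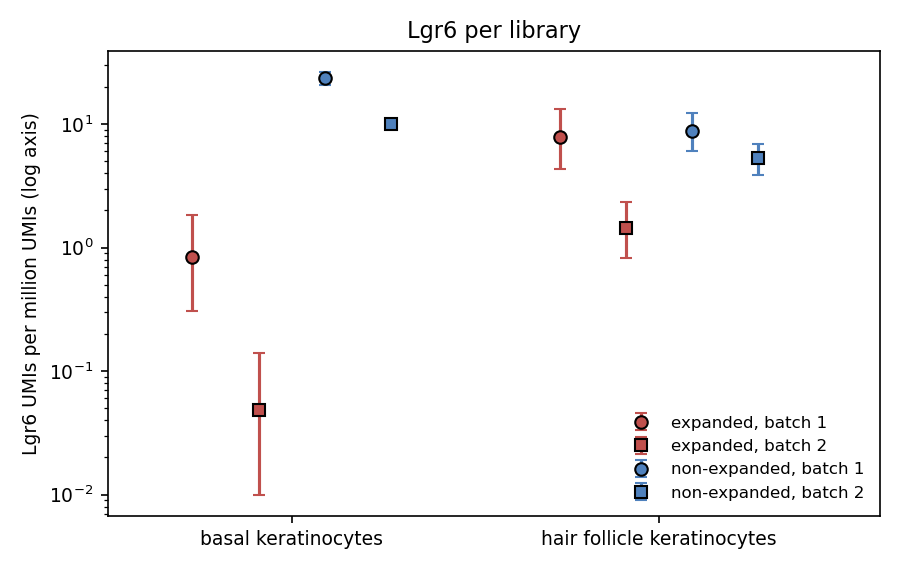
Unscaled CPM of Lgr6 in basal and hair follicle keratinocytes of each library, with 95% counting intervals. Basal levels were 0.843 and 0.048 in expanded and 23.4 and 10.02 in non-expanded libraries.

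The other stem cell, keratin and tension genes chosen beforehand moved less in basal keratinocytes. Log2 fold changes were -0.56 for Lgr4, -0.25 for Lrig1, -0.19 for Krt14, -0.41 for Krt5, 0.74 for Krt1, -0.46 for Krt10, -0.06 for Krt17, 0.75 for Lor, 0.06 for Mki67 and -0.91 for Ccnd1. Of the Hippo and YAP genes, Yap1 had -0.21, Wwtr1 -0.53, Ccn1 -0.23 and Ccn2 -4.43, the last on 1, 1, 14 and 34 UMIs. Axin2 had -1.12, Egfr 0.03, Fos -0.17, Jun -0.15, Piezo1 -0.96, Col17a1 -0.43, Itgb1 -0.52 and Itga6 -0.68. Krt6a (-2.77), Krt16 (-2.10) and Areg (-3.82) fell on average because of non-expanded replicate 2, in which Krt6a stood at 2215 unscaled CPM against 144, 185 and 131 elsewhere. None of these genes passed by edgeR (adjusted p 0.243 for Lgr6 to 0.996 for Krt17). Lgr5 (0, 3, 1 and 0 UMIs) and Ankrd1 (0 in every library) were too rare to test.

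Cycling basal cells formed 38.0 ± 13.3% of expanded and 39.5 ± 5.47% of non-expanded basal cells after thinning (28.5% and 47.4% against 35.7% and 43.4%; exact permutation p = 1). The difference was -1.54 points, -7.12 in batch 1 and 4.04 in batch 2. The level depended on the definition: means were 57.4% of expanded and 59.0% of non-expanded cells at a minimum of 2 UMIs and 16.1% and 15.5% by Mki67 or Top2a. Without thinning it was 15.9 points, a value that followed depth.

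With a preset correlation between genes, 16 of 29 lists passed in basal keratinocytes, with wound, hypoxia and translation genes higher and adhesion, cytoskeleton and differentiation genes lower, but 0 passed with the correlation estimated from the data. Higher were wound and stress keratinocyte genes (camera adjusted p = 7.73e-13; S100a8, S100a9), ribosomal proteins (1.75e-09; Rpl17 0.85, against Rpl22l1 at -0.76), hypoxia response (4.49e-07; Ndufa4l2 1.63, Egln3 2.57), glycolysis (0.00234; Slc2a1 1.19, Pgk1 0.90), NRF2 targets and redox (0.00591; Nqo1 1.71, Slc7a11 2.83), G2 and M phase (0.0318; Cdca3 0.73, Psrc1 0.99) and oxidative phosphorylation (0.0416; Cox6b2 1.596, Cox7a2l 1.003). Lower were actin and myosin cytoskeleton (2.58e-05; Tpm1 -1.90, Cnn2 -2.11), desmosome and adherens junction (8.49e-05; Evpl -1.12, Dsg1a -1.23), hemidesmosome and basement membrane (9.29e-05; Plec -0.76, Dst -0.94) and early differentiation (0.000619; Mt4 -5.32, against Them5 at 3.11). Heat shock (0.0236; Hsph1 -1.27, Hspb1 -0.53), immediate-early genes (0.0241; Klf4 -0.73, Jund -0.62), tight junction (0.0394; Tjp1 -0.45, Cldn4 -1.20), cornified envelope (0.0408; Crct1 -2.23, Aloxe3 -1.69) and Wnt (0.0416; Wnt7b -1.67, Lgr6 -6.36) were lower too. The Wnt list had a median log2 fold change of -0.113 and a mean of -0.408, so its call is not separate from the Lgr6 result. The wound and stress list had a median of 0.614 and a mean of 1.113. Its members Krt6a (-2.77) and Krt16 (-2.10) were lower, because of non-expanded replicate 2. Over that list alone 6 members rose and 0 fell. Leaving out expanded replicate 1, expanded replicate 2, non-expanded replicate 1 or non-expanded replicate 2 kept 14, 9, 11 and 11 of the 16. Direction turned for wound and stress keratinocyte genes in basal keratinocytes without non-expanded replicate 1 (0.374), for G2 and M phase in basal keratinocytes without expanded replicate 2 (0.0833), for cornified envelope and granular layer in basal keratinocytes without non-expanded replicate 2 (0.895), and for immediate-early genes in basal keratinocytes without expanded replicate 1 (0.571) or non-expanded replicate 2 (0.644). Ranges of adjusted p over left-out libraries for these 4 lists were 1.49e-39 to 0.374, 9.57e-09 to 0.581, 9.72e-07 to 0.895 and 1.68e-13 to 0.644.

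The lowest camera adjusted p of a basal list with the estimated correlation was 0.693, and none passed by fry with direction (lowest 0.142). fry without direction passed wound and stress (0.0303), desmosome (0.00523), early differentiation (0.00523) and chemokine (0.0484) lists. No member of any list passed over all genes tested. Over the list alone, 6 wound and stress genes, 5 hypoxia genes and 2 NRF2 genes rose, 2 Wnt genes fell, and 1 early differentiation gene rose and 3 fell. YAP/TAZ targets (0.301) had 1 member lower over the list alone, and Hippo components (0.508), S phase (0.979), Notch (0.979), TGF-beta and BMP (0.706), EGFR and MAPK (0.0798), ribosome biogenesis (0.142) and mitochondrially encoded genes (0.595) did not pass. Cholesterol synthesis (0.232), interferon response (0.693; median -0.07, mean 0.13), unfolded protein response (0.0645), p53 targets (0.196) and chemokines (0.309) did not pass either. The replicate block left out cornified envelope (0.0701) and added EGFR and MAPK (0.00254), cholesterol (0.0204) and unfolded protein response (0.0300), and of the list members above Dsg1a (edgeR adjusted p = 0.0402), Tpm1 (0.0487), Wnt7b (0.0252), Ndufa4l2 (0.0404) and Slc7a11 (0.0404) passed in that fit.

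Krt77 and Krt2 stood far lower in suprabasal keratinocytes of expanded skin, and Serpinb3a, Sprr2a3 and Rnase2b far higher. Of the suprabasal clusters, 2 were strongly skewed between the groups. Cluster 1, with Krt77 and Krt2 among its leading genes, held 41 and 14 expanded and 470 and 335 non-expanded cells, and cluster 7 held 69 and 523 against 4 and 24. Clusters 4, 6 and 9 held many cells of both groups. Cluster 6 held 66 and 688 against 190 and 199, cluster 4 57 and 425 against 10 and 368, and cluster 9 20 and 105 against 28 and 245. Krt77 fell from 959 ± 379 to 5.22 ± 1.30 CPM (log2 fold change -7.56, SE 0.48, edgeR adjusted p = 0.0243), Krt2 from 361 ± 157 to 3.54 ± 1.63 CPM (-6.58, SE 0.54, 0.0406) and Tesc from 82.5 ± 4.72 to 7.18 ± 1.97 CPM (-3.49, 0.0406). Serpinb3a rose from 5.61 ± 0.786 to 197 ± 12.9 CPM (5.12, SE 0.26, 0.0219), Sprr2a3 from 7.07 ± 0.319 to 201 ± 39.2 CPM (4.82, SE 0.28, 0.0219), Rnase2b from 0.728 ± 0.569 to 58.6 ± 10.9 CPM (6.02, 0.0406) and Mgst1 from 11.8 ± 0.311 to 109 ± 23.1 CPM (3.21, 0.0406). Serpinb3a, Sprr2a3 and Rnase2b have near copies in the genome to which some of their reads may belong.

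In suprabasal keratinocytes 8 of 12000 genes tested passed by edgeR, 4 higher and 4 lower (1057 at unadjusted p < 0.05), the 7 above among them. DESeq2 called 259 including all 8, and the fit with the replicate block 20 including all 8. Leaving out expanded replicate 1 gave 9 genes (4 of the 8), expanded replicate 2 1 gene (0 of the 8), non-expanded replicate 1 471 and non-expanded replicate 2 189 (8 of the 8 each). Without expanded replicate 2, Krt77 in suprabasal keratinocytes had an edgeR adjusted p of 0.152 and Serpinb3a in suprabasal keratinocytes 0.104, the highest of ranges from 5.2e-72 and 2.57e-53. Because Krt77 and Krt2 also led suprabasal clusters, the cells were clustered again without any called gene. Krt77, Serpinb3a and Sprr2a3 in suprabasal keratinocytes kept their calls there, at log2 fold changes of -7.45, 5.13 and 4.69. Krt2 in suprabasal keratinocytes (-6.53), Mgst1 in suprabasal keratinocytes (3.15), Tesc in suprabasal keratinocytes (-3.47) and Rnase2b in suprabasal keratinocytes (6.04) did not pass there, with fold changes close to those above. With the block (fold changes from the fit without it) Stfa3 (4.20; 598 ± 258 to 10970 ± 1771 CPM), Alox12e (-5.28), Lce3c (-4.40) and Defb14 (-4.00) passed too. Lce3c and Defb14 rested on non-expanded replicate 2, at 93.8 and 77.0 CPM against at most 3.69 and 3.90 in the other libraries, and Defb14 in suprabasal keratinocytes ranged from -12.27 to 2.81 over left-out libraries, the latter without non-expanded replicate 2.

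**Figure D3:**
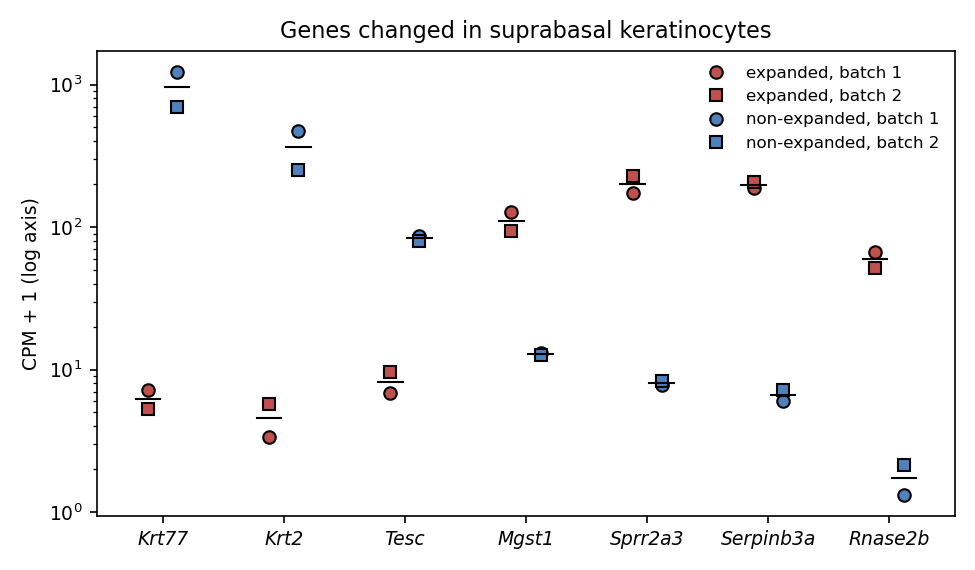
CPM of the 7 named genes past the threshold in suprabasal keratinocytes of each library, with lines at the group means. Krt77 stood at 5.22 CPM in expanded and 959 CPM in non-expanded skin, Serpinb3a at 197 and 5.61 CPM.

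In suprabasal keratinocytes 11 of 29 lists passed with the preset correlation, with hypoxia, glycolysis and wound genes higher and differentiation genes lower, and 0 passed with the estimated one. Higher were hypoxia response (camera adjusted p = 4.86e-09; Ndufa4l2 2.09, Bnip3 2.03), ribosomal proteins (1.31e-06; Rps6 0.71, against Rpl22l1 at -0.74), wound and stress (2.44e-06; Stfa3 4.20, Sprr2a3 4.82) and glycolysis (0.000105; Slc2a1 1.38, Slc16a3 2.58). Lower were early differentiation (3.11e-13; Krt77, Krt2) and cornified envelope (1.33e-10; Flg2 -3.76). Lce1e had 0 and 0 UMIs in expanded and 246 and 150 in non-expanded libraries. Hemidesmosome (0.0175; Dst -1.40, Plec -0.53), cholesterol synthesis (0.0175; Pmvk -0.89, Fdps -1.07), desmosome (0.0483; Dsg1a -0.82, against Cdh3 at 1.20), tight junction (0.0483; Cgn -1.35, Cldn4 -1.64) and heat shock (0.0483; Hsph1 -1.52, Hspb1 -1.07) were lower too. Direction turned for wound and stress keratinocyte genes in suprabasal keratinocytes without non-expanded replicate 1 (0.934; range over left-out libraries 4.06e-25 to 0.934) and for cholesterol synthesis in suprabasal keratinocytes without non-expanded replicate 2 (0.0746; 2.2e-15 to 0.472). Hypoxia response, early differentiation and cornified envelope passed without any 1 library, but such fits leave a single library in a group.

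The lowest camera adjusted p of a suprabasal list with the estimated correlation was 0.471. None passed by fry with direction (lowest 0.0801), and fry without direction passed wound and stress (0.0362) and early differentiation (0.0407). Over the list alone 7 wound genes rose and 2 fell (1 rose over all genes), 6 early differentiation genes fell (2 over all genes), 3 hypoxia genes and 1 glycolysis gene rose, and 1 cornified envelope gene and 2 heat shock genes fell. Actin (0.0527), NRF2 (0.0527; 2 members higher over the list alone), Wnt (0.0861), Hippo (0.135), p53 (0.179; 2 lower), oxidative phosphorylation (0.224), mitochondrially encoded genes (0.224), unfolded protein response (0.224), TGF-beta and BMP (0.379; 1 lower), EGFR and MAPK (0.412) and interferon (0.412) did not pass. Ribosome biogenesis (0.567), immediate-early genes (0.651; median 0.13, mean -0.03), YAP/TAZ targets (0.686), S phase (0.686), G2 and M phase (0.713; median 0.05, tested as lower), Notch (0.713; median -0.01, tested as higher) and chemokines (0.806; median 0.16, tested as lower) did not pass either. The replicate block left out desmosome and heat shock (0.0522) and added actin and NRF2 (0.0306), and Flg2 (edgeR adjusted p = 0.0392) and Lce1e (0.0395) passed in that fit. Leaving out non-expanded replicate 2 gave 7 lists, 6 of the 11 among them.

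Hair follicle keratinocytes gained the hypoxia gene Ndufa4l2, Serpinb3a and Il1f8 in expanded skin. Ndufa4l2 rose from 5.82 ± 1.06 to 131 ± 33.7 CPM (log2 fold change 4.47, SE 0.31, edgeR adjusted p = 0.00758). Serpinb3a had 57 and 976 UMIs in expanded and 0 and 2 in non-expanded libraries (edgeR adjusted p = 0.0268), and Il1f8, below the level set for naming, had 3.91 (SE 0.37, 0.0268). Among the genes past the threshold with the replicate block (fold changes from the fit without it) S100a9 (8.24), S100a8 (8.07), Slurp2 (4.59), Stfa3 (3.83), Serpinb3b (3.51), Endou (3.47), Gjb2 (2.94), Gpx2 (2.79), Ttll7 (2.66) and Rbp2 (2.43) rose as well. Krt77 (-3.32), H2-Q7 (-3.00), Abi3bp (-2.95), Alox12e (-2.70), Pdlim4 (-2.37), Gm32219 (-2.19), Adgrl3 (-1.99), Ccl27a (-1.87), Sprr1a (-1.75), Slc29a1 (-1.75), Tle4 (-1.74) and Fbxo32 (-1.73) fell. Those 3 genes were all that passed of 11591 tested (983 at unadjusted p < 0.05), and DESeq2 called 101 and the block 88. All 3 were called whichever library was left out, but such fits leave a single library in a group. Expanded hair follicle cells carried Krt10 at 6155 and 2094 unscaled CPM against 278 and 967. Once called genes were left out of the clustering genes 0 genes passed by edgeR, but Ndufa4l2 in hair follicle keratinocytes had a log2 fold change of 4.62 there (range of its adjusted p over alternatives 1.60e-38 to 0.939), and the fitted one of Serpinb3a was no smaller.

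Of the lists in hair follicle keratinocytes, added after the data were seen, 14 passed at the preset correlation and 0 at the estimated one (lowest camera adjusted p 0.712; lowest by fry with direction 0.628). Not all of the 14 passed when 1 library was left out, whichever library it was. The groups differed in the mix of hair follicle clusters. Cluster 11, with more Mki67 than the other 2, held 55 and 192 expanded and 473 and 257 non-expanded cells. Cluster 16, richest in Krt10, held 35 and 224 against 236 and 171, and cluster 17 held 6 and 0 against 25 and 77. Cell type marker lists shifted too at the preset correlation. Spinous markers were higher (camera adjusted p = 1.69e-07), and upper hair follicle (0.000888) and bulge markers (0.00082) lower. None of these 3 passed with the estimated correlation (lowest camera adjusted p 0.389). Lists, the genes called in this class and its comparison with basal cells can follow this mix. S phase (4.27e-12), G2 and M phase (4.27e-12), interferon response (0.00316), immediate-early genes (0.00402), ribosome biogenesis (0.00402), Wnt (0.00809), EGFR and MAPK (0.0118) and tight junction (0.0237) were lower. Wound and stress (1.25e-10), hypoxia (2.93e-08), cholesterol synthesis (1.44e-07), glycolysis (6.25e-07), ribosomal proteins (0.0004) and early differentiation (0.00581) were higher. Over the list alone 6 wound genes rose and 1 fell, 3 hypoxia genes rose (1 over all genes), 2 glycolysis genes rose, and 5 early differentiation genes rose and 3 fell. The replicate block added desmosome (0.0259) and NRF2 (0.0112), both higher.

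In all keratinocytes pooled, Krt77 fell from 296 ± 97.4 to 2.75 ± 0.141 CPM (log2 fold change -6.74, edgeR adjusted p = 0.0359) and Serpinb3a rose from 1.75 ± 0.322 to 89.8 ± 7.85 CPM (5.65, 0.0307). They were the 2 genes past the threshold of 14312 (1019 at unadjusted p < 0.05), against 294 by DESeq2, 6 with the replicate block and 0 without expanded replicate 1 or without expanded replicate 2. Leaving out non-expanded replicate 1 gave 55 and non-expanded replicate 2 163.

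Effects of expansion on 34 genes differed between basal and suprabasal keratinocytes, 20 with a higher and 14 with a lower effect in basal cells. These differences can follow the mix of clusters within each class, which was uneven between libraries. Of the 34, 34 were shared with the stricter filter and 11 with doublets kept. Scaling over all libraries kept 4 and response genes kept among the clustering genes 6. The differentiation genes Sprr1a, Lor and Krt2 had lower effects in suprabasal than in basal cells, of which only that on Krt2 passed in suprabasal cells by itself: Sprr1a had 0.94 in basal and -4.27 in suprabasal cells (difference 5.17, edgeR adjusted p = 0.0278), Lor 0.75 and -1.21 (2.35), and Krt2 -2.02 and -6.58 (4.53, 0.0057). Sprr2h (2.03 and -2.37), Them5 (3.11 and 0.44), Homer2, Tdh and Gm20627 also had higher effects in basal cells. Palld (-0.34 and 2.90; difference -3.28, 0.0057), Stfa2 (-0.87 and 2.16), Stfa3 (2.46 and 4.20), Nqo1 (1.71 and 4.45), Thbs1 (1.36 and 3.58), Gm94, Foxq1 and Akr1b8 had higher effects in suprabasal cells. Without the library block 0 genes passed (165 at unadjusted p < 0.05), and DESeq2 called 62, of which 33 were shared. Leaving out expanded replicate 1 gave 52 genes, expanded replicate 2 11, non-expanded replicate 1 416 and non-expanded replicate 2 268.

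Against hair follicle cells, an added comparison, 65 genes differed, 20 with a higher and 45 with a lower effect in basal cells. The count rested on the clustering. With response genes kept among the clustering genes 0 genes passed, and with scaling over all libraries 41, of which 29 were shared. The stricter filter gave 33, all shared, and doublets kept 161, with 65 shared. Lcn2 rose in basal cells and little in hair follicle ones (6.60 and 1.03; difference 4.96, edgeR adjusted p = 0.000334), and Cyp1b1 (4.48), Defb1 (3.25), Sostdc1 (3.11), Sult5a1 (3.05), Fst (3.03), Aadac (2.17) and Irx4 (2.12) had higher effects in basal cells. Mt4 (-5.32 and 0.92), Krt16 (-2.10 and 1.73), Krt6a (-2.77 and 0.70), Ndufa4l2 (1.63 and 4.47), Sprr1b, Il1rn, Gpx2 and Klk8 had lower ones. Without the block 0 genes passed (554 at unadjusted p < 0.05), DESeq2 called 162 (63 shared), and leaving out each library in the order above gave 143, 14, 432 and 546.

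T cells (30, 19, 108 and 80) and antigen-presenting cells (3, 0, 7 and 62) were too few to test.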

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

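The difference between basal and suprabasal effects was a test chosen beforehand, whereas the comparison with hair follicle keratinocytes and the tests of explanations for Lgr6 were chosen only after the results were seen. Effects of expansion differed between basal and suprabasal keratinocytes for 34 genes by the edgeR interaction test, and can follow the mix of clusters within each class. Higher in basal cells were the effects on Sprr1a (5.17), Krt2 (4.53), Sprr2h (4.48), Them5 (2.83), Homer2 (2.74), Tdh (2.61), Gm20627 (2.35) and Lor (2.35). Lower were those on Palld (-3.28), Stfa2 (-2.98), Nqo1 (-2.59), Thbs1 (-2.13), Gm94 (-1.91), Foxq1 (-1.87), Stfa3 (-1.66) and Akr1b8 (-1.55). edgeR adjusted p of these 16 genes lay between 0.0057 and 0.0441.

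Effects in basal and hair follicle keratinocytes differed for 65 genes by the same test, and can follow the mix of hair follicle clusters, which differed between the groups. With response genes kept among the clustering genes 0 genes passed. Higher in basal cells were those on Lcn2 (4.96), Cyp1b1 (4.48), Defb1 (3.25), Sostdc1 (3.11), Sult5a1 (3.05), Fst (3.03), Aadac (2.17) and Irx4 (2.12). Lower were those on Sprr1b (-6.16), Mt4 (-5.93), Krt16 (-4.42), Krt6a (-3.64), Il1rn (-3.34), Gpx2 (-3.32), Klk8 (-2.96) and Ndufa4l2 (-2.81), with edgeR adjusted p up to 0.0452. Krt6a and Krt16 stood far higher in basal cells of non-expanded replicate 2 than in the other 3 libraries, and leaving that library out gave 546 genes. Lgr6 (-5.14) is added because it is the gene named in the study title, after its value was seen.

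The tables argued against 3 technical causes, each as the whole cause, of the lower Lgr6 in expanded basal cells. Depth was excluded by thinning: the difference of detection shares was -3.404 points, with limits of 0.847% and 0.125% in the expanded libraries and no non-expanded lower bound under 1.953%. A different mix of basal clusters was excluded, since the upper bound of the expanded to non-expanded ratio was at most 0.124 in all 7 basal clusters. An allele or genotype difference would lower Lgr6 alike in hair follicle cells. The ratio there was 0.903 (0.446 to 1.73) in batch 1 but 0.275 (0.146 to 0.493) in batch 2. The basal effect minus the hair follicle effect was -5.14 (SE 0.585, edgeR adjusted p = 0.0194). This difference did not pass without the library block (edgeR adjusted p = 0.9999). With response genes kept among the clustering genes 0 genes passed in this comparison. A part from this cause therefore stays open. A candidate explanation that also stays open is that expansion lowers Lgr6 transcripts or removes Lgr6-expressing cells in the interfollicular epidermis, a hypothesis that came from these 4 libraries; neither part of it was tested.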

How the results depend on the processing

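Alternatives that leave out swapped barcodes or mitochondrial and ribosomal clusters, change the clustering genes or scaling, or call cycling by Mki67 or Top2a were chosen after seeing the data. Of 3251 alternative values of named genes and lists, 2487 kept direction and side of the threshold, 444 became stronger, 260 weaker, 46 reversed and 14 moved. The cause was not tested where a result changed. Counts of genes changed were, in basal keratinocytes (0), 236 by DESeq2, 136 with the replicate block, 532 without the filter on low counts, 25 after thinning to 2000 UMIs, and 2 each with RLE size factors, Leiden resolution 0.5 and without swapped barcodes (leaving out 1 library 18 to 920). In suprabasal keratinocytes (8) they were 259, 20, 729 and 22 for the first 4 of these, 3 with called genes left out of the clustering genes, 3 with clustering scaled over all libraries and 4 with response genes kept (1 to 471). In hair follicle keratinocytes (3) they were 101, 88, 492 and 18, then 5 with the stricter filter, 17 with doublets kept, 18 at resolution 0.5, 0 with called genes left out, 1 with scaling over all libraries and 0 with response genes kept (60 to 265). In all keratinocytes (2) they were 294, 6, 685 and 26, and 1 with scaling over all libraries (0 to 163). The basal and suprabasal interaction (34) gave 0 without the block, 62 by DESeq2, 370 without the filter, 12 with doublets kept, 15 with called genes left out, 6 with scaling over all libraries and 7 with response genes kept (11 to 416). The basal and hair follicle interaction (65) gave 0 without the block, 0 with response genes kept, 162 by DESeq2 and 786 without the filter. It gave 33 with the stricter filter, 161 with doublets kept, 139 at resolution 0.5 and 41 with scaling over all libraries. With 1 library left out its group has a single library, assumed to vary like the others, so passing in such a fit is not evidence of robustness.

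Lists past the threshold were 0 in both classes with the estimated correlation. In basal cells (16) they were 11 after thinning and 11 without clusters led by mitochondrial or ribosomal RNA. With response genes kept they were 12 in basal cells, 10 of them shared. In suprabasal cells (11) these 3 alternatives gave 11 (8 shared), 12 (11 shared) and 10 (9 shared). Over left-out libraries, camera adjusted p in basal cells reversed within 9.566e-09 to 0.5808 for G2 and M phase (0.6645 with response genes kept), 9.721e-07 to 0.8949 for cornified envelope, 1.678e-13 to 0.644 for immediate-early genes and 1.488e-39 to 0.3739 for wound and stress genes, and in suprabasal cells 2.2e-15 to 0.4721 for cholesterol synthesis and 4.055e-25 to 0.9339 for wound and stress. Share differences reversed for basal cells with scaling over all libraries (4.394 points) and response genes kept (0.473; left-out libraries -10.491 to -7.959) and for suprabasal cells with scaling over all libraries (-4.017; 8.305 to 14.805). In both clusterings the naming rule put keratinocyte-like cells outside their class. With response genes kept, clusters 12 and 10 were high in Krt14 and Krt5. Cluster 12 was named neutrophil, with 39 and 105 expanded and 74 and 823 non-expanded cells. Cluster 10 was named hair follicle, with 26 and 344 against 96 and 478 cells. How far this naming made the reversals was not tested. Hair follicle shares ranged from -9.331 to -0.643 and the Lgr6 share from -4.28 to -2.529. T cells gave 0.332 with the stricter filter (-1.921 to 1.502), and cycling 15.888 without thinning, which follows depth, and 0.627 by Mki67 or Top2a (-10.985 to 7.901).

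Single genes reversed as follows. Ccn1 in basal keratinocytes had 0.1545 with scaling over all libraries (left-out libraries -1.43 to 0.77) and Lrig1 in basal keratinocytes 0.01366 (-0.81 to 0.23). Mki67 in basal keratinocytes had -0.1058 there and -0.3453 with response genes kept (-0.57 to 0.58). Jun in basal keratinocytes had 0.05259 and 0.1402 under these 2, and 0.1045 with the replicate block (-0.96 to 1.42), and Fos 0.3092 with response genes kept (-1.66 to 0.55). Egfr in basal keratinocytes had -0.05884 after thinning and -0.001422 with the stricter filter (-0.07255 to 0.19). Krt14 in basal keratinocytes had 0.007191 after thinning (-0.45 to 0.18) and Krt17 0.2949 (-2.19 to 0.75). Areg in basal keratinocytes (-5.92 to 1.65), Krt10 in basal keratinocytes (-2.00 to 0.30), Krt1 (-0.34 to 1.39), Krt16 (-3.01 to 1.89), Krt6a (-3.65 to 0.41), Cldn4 in basal keratinocytes (-1.99 to 0.03388), Itgb1 (-1.04 to 0.40), Lgr4 (-1.02 to 0.10) and Yap1 (-0.46 to 0.13) reversed over left-out libraries alone. In suprabasal cells so did Defb14 in suprabasal keratinocytes (-12.27 to 2.81), Fdps in suprabasal keratinocytes (-1.68 to 0.04387) and Pmvk (-1.45 to 0.05916). The block changed no other call than those given in the results. Alternatives for the gene tests in T cells and antigen-presenting cells and for the comparison of cells with an Lgr6 UMI were not run, because cells were too few for these tests.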

Other observations

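All tests in this part were chosen only after the results were seen. Non-expanded replicate 2 stood apart from its group partner: 80 genes were at least 4-fold higher than in non-expanded replicate 1 in basal keratinocytes. Among them Krt6a stood at 2215 unscaled CPM (144, 185 and 131 in expanded replicates 1 and 2 and non-expanded replicate 1), Mmp3 at 155 (15.04, 6.01 and 14.1) and Areg at 105 (0.84, 5.48 and 1.18). A batch difference shared by both groups stays open: the genes had a median log2 difference of 1.064 between the expanded replicates (upper quartile 1.886) and 2.857 between the non-expanded ones (lower quartile 2.348), but genes chosen on the latter difference would show less in the former by selection alone. More cells of basal cluster 3 as the whole cause were argued against by a median difference of 1.495 or more within 3 other basal clusters. The genes were chosen on sums that include these cells, which favours a difference within them, so this cause was not excluded. A mislabelled library from expanded skin was argued against by 29 genes that differed in batch 1, on which this library lay a median of 0.312 of the way to the expanded level (quartiles 0.099 and 0.545) and expanded replicate 2 0.987. A mixed sample, handling and a difference between animals stay open, and no biological explanation was tested.

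The tdTomato reporter was found in T cells at 101, 177, 180 and 164 unscaled CPM in the 4 libraries, against 631, 767, 720 and 857 in basal cells. After thinning, a tdTomato UMI was found in 47.6% of expanded and 54.0% of non-expanded basal cells, and in 22.2% and 29.4% of T cells. Free keratinocyte RNA was excluded as the whole cause, since tdTomato in T cells was at least 4.67 times (lower bound 3.39) as large a fraction of its basal level as Krt14 and Krt5. Droplets shared with a keratinocyte were argued against by the 54 T cells without a UMI of Krt14, Krt5, Krt1 or Krt10, of which 38.89% (25.9 to 53.1) had a tdTomato UMI; 40 of them came from non-expanded replicate 1 (32.5%), 9 and 4 from expanded replicates 1 and 2 (55.6% and 75%), and 1, without a tdTomato UMI, from non-expanded replicate 2, about which they say nothing. Transcripts of the reporter locus before recombination, or sequence shared with other transcripts, cannot be told apart from recombined reporter (lowest T cell level 100.9), because no animal without Cre was analysed here, so tdTomato was not used to trace Lgr6 cells.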
